A study of Mus musculus with 6 samples.

How the data were processed

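Messenger RNA was measured by bulk RNA sequencing in 6 libraries of flow-sorted marginal zone B cells, 3 from CD55KO and 3 from WT mice. Per the labels' protocols, RNA was extracted with an RNeasy micro kit and libraries were made with the SMARTer Ultra Low RNA kit, which does not mark strand. The values are estimated counts per gene, as deposited by the authors, with no scaling to a common total. The submitters' processing notes name DRAGEN, edgeR and limma without versions or roles. The aligner settings, genome build and annotation are not given in the sources used here. Between 30.9 and 31.9% of the nonzero values of a library were not whole numbers (tolerance 0.005). Genotype and replicate number of each library came from the labels.

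The deposited table held 55774 rows for 55487 Ensembl gene IDs. The 168 IDs that stood in more than 1 row had identical values there, and the 287 repeated rows were removed. Counts were then rounded to whole numbers. Positions were taken from GENCODE M21 (GRCm38) through the gene ID, where 55141 IDs (99.4%) were found, and 98.9% of these had the same number of transcripts as in the deposited table. Total counts were 26680683, 24961343 and 29209647 for CD55KO replicates 1 to 3 and 20056111, 30784090 and 29209435 for WT replicates 1 to 3. A count of 0 allows up to 3 counts, which is 0.0958 to 0.146 CPM depending on the library, and covers counting error only. Replicates of a genotype differed by far more than sampling noise (chi-square per degree of freedom 14.2 to 36.1), so none was counted as a duplicate.

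Genotypes were compared with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr at its defaults (minimum count 10, minimum total 15), which left 13794 genes and removed 41693. TMM scaling, robust dispersion estimates and the robust quasi-likelihood F-test were used with genotype alone in the model. P-values were adjusted by Benjamini and Hochberg and the threshold was an adjusted p of 0.05. CPM values are scaled by TMM, and log2 fold changes are CD55KO against WT. Group values are means with the SD over 3 libraries.

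The 34 gene lists covered complement, B cell subsets, B cell signalling, stress, metabolism, proliferation and other cell types. Those with at least 5 tested members, 32 lists, were tested with camera in limma 3.58.1 with a preset correlation between genes of 0.01, adjusted over the lists. Members were also counted by their own tests, over all genes and adjusted over the list alone. Camera with an estimated correlation and fry were alternatives. Called genes within 10 Mb of Cd55, without Cd55, were compared with those elsewhere by Fisher's exact test. Immunoglobulin variable segments were counted as a class. Shares of counts were compared by exact permutation tests.

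The named genes are Cd55 and, among genes past the threshold with libraries that do not overlap and a mean of at least 5 CPM, the 12 with the largest rise and the 12 with the largest fall. Predicted genes, unnamed genes with names ending in Rik, and immunoglobulin segments were passed over. 9930111J21Rik2, a gene with a name of the same kind, was kept only because its name does not end in Rik. From each list up to 4 members past the threshold were named, or, where none passed, the 2 with the smallest p. Of the genes past the threshold, 13 higher and 30 lower ones met the conditions. Genes named outside this rule are pointed out where they appear, or are members counted only when adjusted over the list alone, and were chosen after their values were seen. The result of a member of the interferon list is not reported here. The lists, the tests described so far, the naming rule and the other settings not said to be added later were fixed before the data were examined. The limits of the test on simulated data and part of the tests of explanations were not, as pointed out where they appear.

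The other settings tried were the replicate number as a block, DESeq2 size factors, library totals as the only scaling, the DESeq2 1.42.0 Wald test, limma-voom with and without quality weights, no count filter, a stricter filter (50 counts in 3 libraries), leaving out immunoglobulin or mitochondrial genes, a test against a fold of 1.5, a non-robust fit, windows of 5 and 20 Mb and leaving out each library in turn. Leaving out the genes near Cd55, leaving Cd55 out of its list and a haemoglobin score as a covariate were added after seeing the data.

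The gene test was tested on simulated data with 200 changed genes, in 6 simulations with gene-wise and 6 with trended dispersions, on 13500 to 13564 genes. A first version with 1 simulation was stopped by a limit set in advance on the share of unchanged genes among the calls, which came to 16.9%. The limit was then replaced by limits on the p-values of unchanged genes and on recovery, and all 6 simulations of each kind are given here. With gene-wise dispersions, 50.7% of genes changed 1.5-fold, 70.6% of those changed 2-fold and 89.4% of those changed 4-fold were recovered, none with the wrong sign, and 96 of 938 calls (10.2%, from 7.5 to 16.9% per simulation) were unchanged genes. With trended dispersions the shares recovered were 52.7, 74.4 and 91.2%, and 43 of 915 calls (4.7%, from 2 to 9.6%) were unchanged genes. The share of false calls can thus exceed the nominal level where dispersions vary between genes. In the simulated lists of 20 genes with independent members, camera called 0 of 30 unshifted lists and the 1 list shifted 1.3-fold. Independent members do not show how camera behaves on correlated genes.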

Results

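Marginal zone (MZ) B cells, splenic B cells with high levels of complement receptor 2 that respond early to blood-borne antigens, were isolated from 14-week-old mice by negative selection for B cells followed by flow sorting. RNA was sequenced in 3 libraries from CD55-knockout (CD55KO) mice and 3 libraries from wild-type (WT) C57BL/6 mice. CD55, also called decay-accelerating factor, is a membrane protein that limits complement activation on the cell that carries it. The comparison asks how MZ B cells that lack CD55 differ in gene expression from WT MZ B cells. The labels do not say whether the libraries of a genotype came from separate mice, so the p-values measure only the spread between these libraries, which may be technical. Total counts were 26680683, 24961343 and 29209647 for CD55KO replicates 1 to 3 and 20056111, 30784090 and 29209435 for WT replicates 1 to 3. Between 13330 and 13950 genes had at least 10 counts in a library. WT replicate 1, the shallowest library, stood apart from the other 5 on the first principal component (28.8% of the variance). The genotypes separated on the second component (22.5%).

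Cd55 transcripts were low in all 3 CD55KO libraries. Cd55 (ENSMUSG00000026399) lies on the minus strand of chromosome 1, from position 130439027 to 130462744 (GRCm38), and had 7.53 ± 1.36 CPM (TMM-scaled) in CD55KO and 118 ± 7.69 CPM in WT (SD, n = 3). Before rounding, the counts were 244, 154 and 212 in CD55KO replicates 1 to 3 and 2580, 3715 and 3096 in WT replicates 1 to 3. The log2 fold change of CD55KO against WT was -3.96 ± 0.11 (SE), with an adjusted p of 3.9e-12 in edgeR's quasi-likelihood test. The level left in CD55KO was 6.41% of that in WT (95% interval of the fitted fold change 5.49 to 7.48%). Which part of the gene is deleted is not given in the sources used here, so it is open whether the remaining counts lie on retained exons. As a check on the samples, Xist had 2946 to 5163 counts in each of the 6 libraries, while Ddx3y, Eif2s3y and Kdm5d had 0 counts in all of them, which allows up to 0.146 CPM in the shallowest library. Uty had 2 counts in WT replicate 2 and 0 in the other libraries. Such limits cover counting error only.

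Few genes passed the threshold between CD55KO and WT MZ B cells. Of 13794 genes tested, 55 passed an adjusted p of 0.05, of which 19 were higher and 36 lower in CD55KO. An unadjusted p under 0.05 was found for 1186 genes. In the simulated data with gene-wise dispersions 50.7% of genes changed 1.5-fold were recovered, so further genes may differ. Each simulation held 200 changed genes, and where fewer genes change the share recovered may be lower. The largest rise among the named genes was that of Cxcr4, the receptor for the chemokine CXCL12, which had 13.1 ± 4.38 CPM in CD55KO and 4.0 ± 0.81 CPM in WT (log2 fold change 1.70 ± 0.25 SE, adjusted p = 0.0092). Krtcap3 rose from 6.90 ± 0.33 to 13.5 ± 0.85 CPM (log2 fold change 0.97 ± 0.14 SE, adjusted p = 0.0020). Rbm3, which encodes a cold-inducible RNA-binding protein, rose from 151 ± 3.99 to 219 ± 4.51 CPM (log2 fold change 0.53 ± 0.07 SE, adjusted p = 0.0014). Dynlt1b, a dynein light chain gene, rose 1.72-fold (adjusted p = 6.0e-05). Csrp1, Arl2bp, Srgap2, Anxa1, Tmem71, Emp3, Pdlim1 and Mcoln2 rose by 1.44-fold to 1.61-fold, among them Anxa1, which encodes the phospholipid-binding protein annexin A1.

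Among the genes that fell, 9930111J21Rik2 went from 214 ± 17.2 CPM in WT to 56.6 ± 6.17 CPM in CD55KO (log2 fold change -1.92 ± 0.09 SE, adjusted p = 2.2e-09). Rnpep, which encodes aminopeptidase B, fell from 34.8 ± 3.44 to 11.3 ± 2.49 CPM (log2 fold change -1.62 ± 0.14 SE, adjusted p = 4.0e-05). Pik3c2b, which encodes a class II phosphoinositide 3-kinase, fell from 46.3 ± 2.63 to 21.7 ± 2.15 CPM (log2 fold change -1.09 ± 0.10 SE, adjusted p = 1.3e-05). Fam177a, Srp54b, Lman2l, H2bc4, H2-Q7, Sdf2l1, Creld2, Zc3h11a and Banp fell with log2 fold changes from -1.03 to -0.71. Srp54b encodes a subunit of the signal recognition particle and H2bc4 a histone. 9930111J21Rik2, Srp54b, H2-Q7, H2bc4 and Dynlt1b have near-identical relatives that could share their reads, so their values are uncertain.

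**Figure D1:**
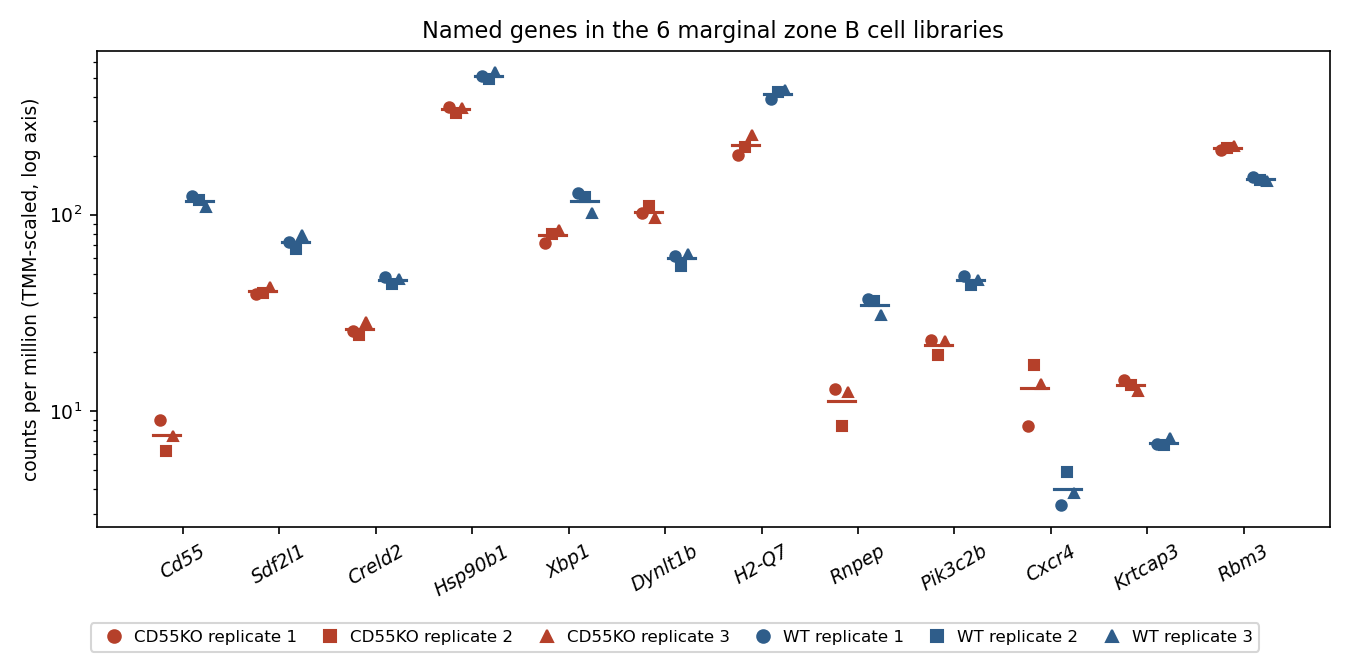
TMM-scaled CPM (log axis) of 12 genes in each CD55KO library (red) and each WT library (blue), with horizontal bars at the means of 3 libraries. For each of these genes the CD55KO libraries lie all above or all below the WT libraries, as for Cd55 at 7.53 CPM on average in CD55KO and 118 CPM in WT. The naming rule required this of all but Cd55, Hsp90b1 and Xbp1.

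For each of the 55 genes the libraries of the genotypes did not overlap, a separation that 14.1% of the tested genes showed and that chance gives to 10%. All 55 kept their sign in each of the 6 fits that left out 1 library, which such a separation leads to by itself. Of the 55, 23 passed in all 6. Of the named genes, Krtcap3, Dynlt1b, Rbm3, 9930111J21Rik2, Rnpep, Pik3c2b, Fam177a, Srp54b, Lman2l, H2-Q7, Sdf2l1, Creld2 and Cd55 passed in all 6. Cxcr4 did not pass without CD55KO replicate 3, WT replicate 1 or WT replicate 3 (highest adjusted p 0.130, without WT replicate 3). Emp3 did not pass without CD55KO replicate 2 (0.0500013), nor Mcoln2 without WT replicate 2 or 3 (up to 0.0527). Pdlim1, H2bc4, Zc3h11a and Banp passed in 3 of the 6 fits, with adjusted p up to 0.138 without CD55KO replicate 2, 0.144 without CD55KO replicate 3, and 0.166 and 0.191 without WT replicate 3, in that order. Tmem71 passed in 2 fits (up to 0.0962, without WT replicate 3). Csrp1, Arl2bp, Srgap2 and Anxa1 passed in 1 fit each, with adjusted p up to 0.134 and 0.242 for Csrp1 and Anxa1 without CD55KO replicate 2, 0.182 for Arl2bp without WT replicate 3 and 0.115 for Srgap2 without WT replicate 1. By limma-voom, Srgap2 (0.0740), Anxa1 (0.158) and Pdlim1 (0.0514) were not called. Without WT replicate 3, 12 genes were called higher instead of 19.

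Genes near Cd55 on chromosome 1 were called far more often than genes elsewhere. Within 10 Mb of Cd55, with Cd55 itself left out, 13 of 115 tested genes passed (11.3%), 7 higher and 6 lower in CD55KO, against 41 of 13678 genes elsewhere (0.300%). The 13 included Cxcr4 at 1.85 Mb from Cd55, Srgap2 at 0.823 Mb, Pik3c2b at 2.58 Mb, Zc3h11a at 3.16 Mb, Rnpep at 4.80 Mb and Csrp1 at 5.26 Mb. Fcmr, which encodes the Fc receptor for IgM and lies at 0.403 Mb, fell from 520 ± 64.7 to 368 ± 20.9 CPM (log2 fold change -0.50 ± 0.10 SE, adjusted p = 0.028). Gm37109, Gm37283 and Gm16083, predicted genes at or within 0.0110 Mb of Cd55, rose from 0.139 ± 0.164, 0.227 ± 0.073 and 0.0556 ± 0.0497 CPM in WT to 6.84 ± 0.68, 5.87 ± 1.00 and 2.53 ± 0.59 CPM in CD55KO. Cd55os and Gm15675, next to Cd55, fell, and Gm37949 at 4.34 Mb rose. Fcmr, Cd55os and the predicted genes were named after their values were seen. Fcmr passed in 2 of the 6 fits without 1 library, not without CD55KO replicate 2 or 3 or WT replicate 2 or 3 (adjusted p up to 0.217, without CD55KO replicate 2), and was not called by limma-voom. Cd55os did not pass without CD55KO replicate 3 or WT replicate 2 (up to 0.0618), and neither DESeq2 nor limma-voom called it.

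The odds ratio of being called within 10 Mb of Cd55 against elsewhere was 42.3 (95% interval 20.2 to 83.6, Fisher's exact test, two-sided, p = 3.9e-16). Without CD55KO replicate 3, WT replicate 2 or WT replicate 3, the number of called genes near Cd55 was 8 each time. Gm16083 overlaps Cd55 on the opposite strand and Cd55os is annotated as antisense. Gm37109 and Gm37283 lie within Gm16083, and Gm15675 lies within Cd55os. The library kit does not mark strand, so reads from overlapping genes cannot be told apart and these values are uncertain. Fisher's test counts such genes as independent, so their calls may raise the odds ratio.

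**Figure D2:**
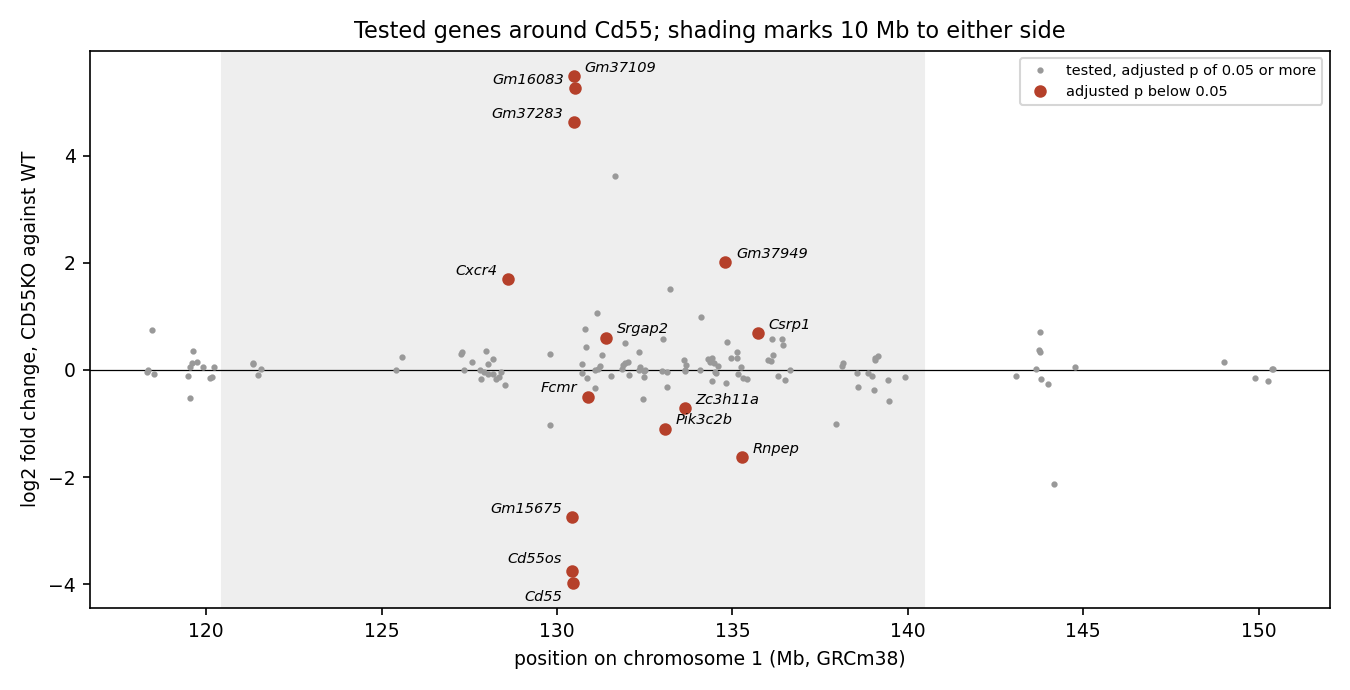
Log2 fold change (CD55KO against WT) of the tested genes within 20 Mb of Cd55, by position on chromosome 1 (Mb, GRCm38), with genes past an adjusted p of 0.05 in red, other genes in grey and 10 Mb to either side shaded. Besides Cd55, 13 genes are red, 7 above and 6 below 0, and all of them lie in the shaded part.

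Of 22 tested members of the unfolded protein response list, which holds genes for protein folding in the endoplasmic reticulum (ER), 9 fell and 13 did not pass, 4 of them with positive log2 fold changes, while 11 fell when adjusted over the list alone. By camera with a preset correlation between genes the list was lower than other genes (median log2 fold change -0.29, adjusted p = 7.6e-19), but not with an estimated one (adjusted p = 0.302 with an estimated correlation), and fry did not call it (0.0671). Sdf2l1, an ER co-chaperone gene, fell from 72.6 ± 6.03 to 40.6 ± 1.80 CPM (log2 fold change -0.84 ± 0.08 SE, adjusted p = 4.5e-05), and Creld2, which is induced by ER stress, from 46.6 ± 2.11 to 26.1 ± 1.98 CPM (adjusted p = 9.2e-05). Hsp90b1, the HSP90 protein of the ER, fell from 511 ± 21.1 to 345 ± 12.9 CPM (log2 fold change -0.57 ± 0.08 SE, adjusted p = 0.0023), and Xbp1, a transcription factor of the unfolded protein response and of plasma cells, from 118 ± 14.0 to 78.5 ± 6.21 CPM (log2 fold change -0.59 ± 0.09 SE, adjusted p = 0.0047). The other members that fell, named after their values were seen, were Dnajb11, Pdia6, Pdia3, Manf and Calr, with log2 fold changes from -0.51 to -0.44. These 5 passed in 4, 4, 1, 2 and 1 of the 6 fits without 1 library, in that order, and neither without CD55KO replicate 2 nor without WT replicate 3, where 4 members fell, Sdf2l1, Creld2, Hsp90b1 and Xbp1 (adjusted p of the 5 up to 0.211, for Calr without CD55KO replicate 2). Manf was not called by limma-voom. Over 8 plasma cell transcripts the mean log2 CPM was 2.32, 2.29 and 2.33 in CD55KO replicates 1 to 3 and 3.36, 3.04 and 2.56 in WT replicates 1 to 3.

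All 14 tested members of the heat shock and chaperone list had negative log2 fold changes. None passed over all genes by edgeR, where 6 had an unadjusted p under 0.05, while 3 passed by DESeq2 and 1 by limma-voom. The count adjusted over the list alone was 5 lower. Hsph1, an HSP110 gene, had 35.9 ± 7.71 CPM in CD55KO and 68.9 ± 7.91 CPM in WT (log2 fold change -0.94 ± 0.16 SE, adjusted p = 0.054). Hspa8, the constitutive HSP70 of the cytosol, had 3192 ± 580 and 4544 ± 557 CPM (log2 fold change -0.51 ± 0.13 SE, adjusted p = 0.191). The list was lower by camera (median log2 fold change -0.30, adjusted p = 2.0e-09; adjusted p = 0.411 with an estimated correlation), although the mean log2 CPM of its members in WT replicate 1, 6.15, lay within the CD55KO range of 5.73 to 6.18.

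**Figure D3:**
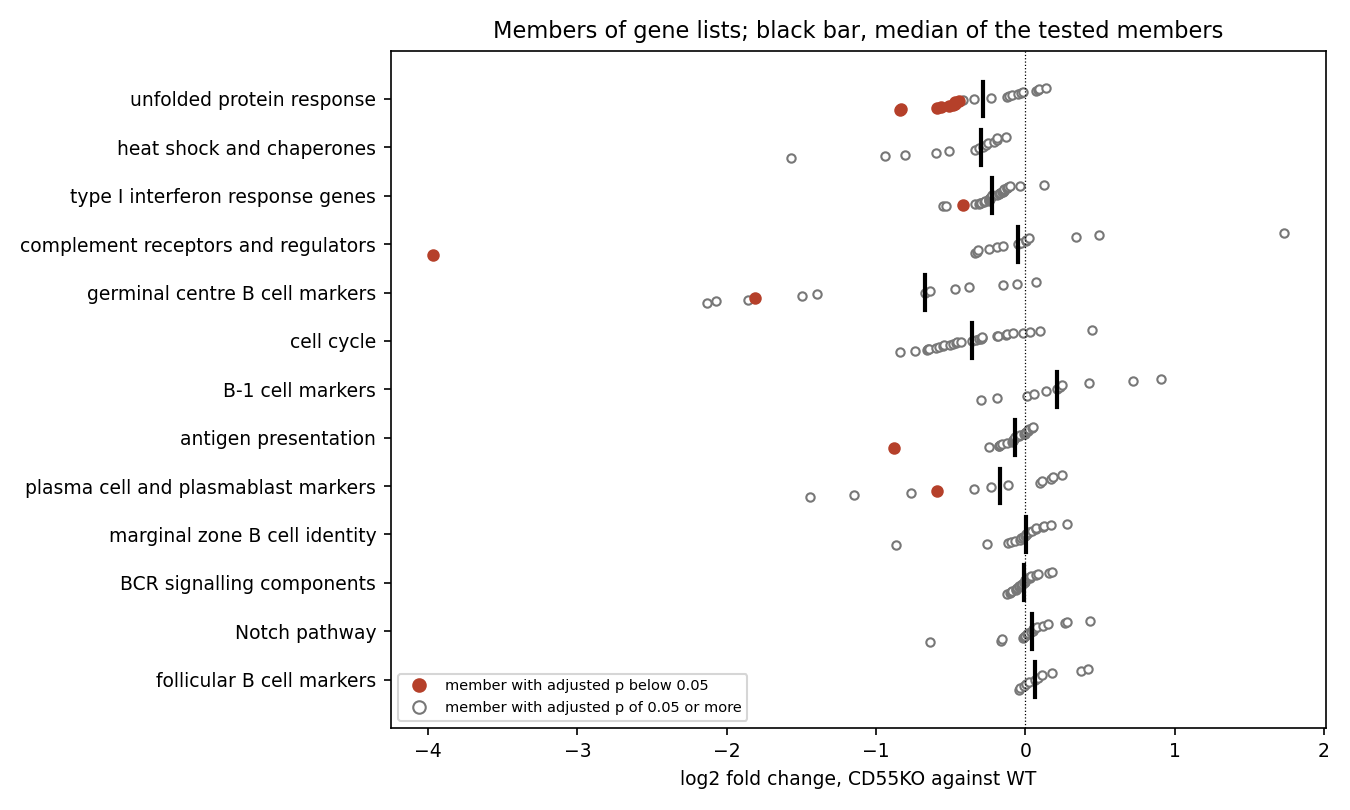
Log2 fold change (CD55KO against WT) of each tested member of the 9 lists called by camera with the preset correlation and of 4 B cell lists that were not called, with members past an adjusted p of 0.05 in red and black bars at the medians. In the unfolded protein response list 9 of 22 members are red, and in the complement list Cd55 is the only one.

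Of 34 tested type I interferon response genes, 33 had negative log2 fold changes, with a median of -0.22. The mean log2 CPM of the list was 4.75, 4.83 and 4.38 in CD55KO replicates 1 to 3 and 4.85, 4.93 and 4.87 in WT replicates 1 to 3. The list was lower by camera (adjusted p = 1.2e-08; adjusted p = 0.476 with an estimated correlation). CD55KO replicate 3 stood apart from the other 5 libraries, and without it the difference between the genotypes in that mean went from -0.23 to -0.09 (camera adjusted p = 0.0126).

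In the antigen presentation list 1 of 24 tested members fell, over all genes and adjusted over the list alone. It was the class Ib MHC gene H2-Q7, with 226 ± 27.9 CPM in CD55KO and 414 ± 24.4 CPM in WT (log2 fold change -0.88 ± 0.10 SE, adjusted p = 9.9e-05). The median of the list was -0.07 (camera adjusted p = 0.014; adjusted p = 0.669 with an estimated correlation). The list was not called without CD55KO replicate 1 (adjusted p = 0.0724), CD55KO replicate 2 (0.0616) or WT replicate 3 (0.414).

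Of 13 tested germinal centre (GC) markers 12 had negative log2 fold changes, with a median of -0.67. Gcsam, a GC-associated signalling adaptor gene, was the 1 member that fell over all genes, from 3.74 ± 1.26 to 1.06 ± 0.48 CPM (log2 fold change -1.81 ± 0.36 SE, adjusted p = 0.034). With p-values adjusted over the list alone 2 fell, Gcsam and Nuggc, the latter named after its values were seen. The list was lower by camera (adjusted p = 1.8e-07; adjusted p = 0.328 with an estimated correlation). Gcsam did not pass in any of the 6 fits without 1 library (adjusted p up to 0.161, without WT replicate 1), nor by limma-voom (0.120). Without WT replicate 2, 3 other members fell over all genes, and none did in the remaining fits.

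Of 29 tested cell cycle genes, 26 had negative log2 fold changes, with a median of -0.36. None passed by edgeR, over all genes or adjusted over the list alone, nor by DESeq2 or limma-voom, and 8 had an unadjusted p under 0.05. Mcm5, a gene of the replicative helicase, had 47.0 ± 4.18 CPM in CD55KO and 60.4 ± 9.86 CPM in WT (adjusted p = 0.275), and the cyclin gene Ccnd3 had 58.8 ± 7.31 and 73.7 ± 9.19 CPM (adjusted p = 0.309). The list was lower by camera (adjusted p = 7.2e-07; adjusted p = 0.538 with an estimated correlation), but not without WT replicate 1 (adjusted p = 0.147). That library had a mean log2 CPM of 4.95 over the cell cycle list, against 4.08 to 4.30 in the other 5. It also had the highest mean over 8 GC transcripts, 3.26, where WT replicate 2, at 1.47, lay within the CD55KO range of 0.43 to 1.54.

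**Figure D4:**
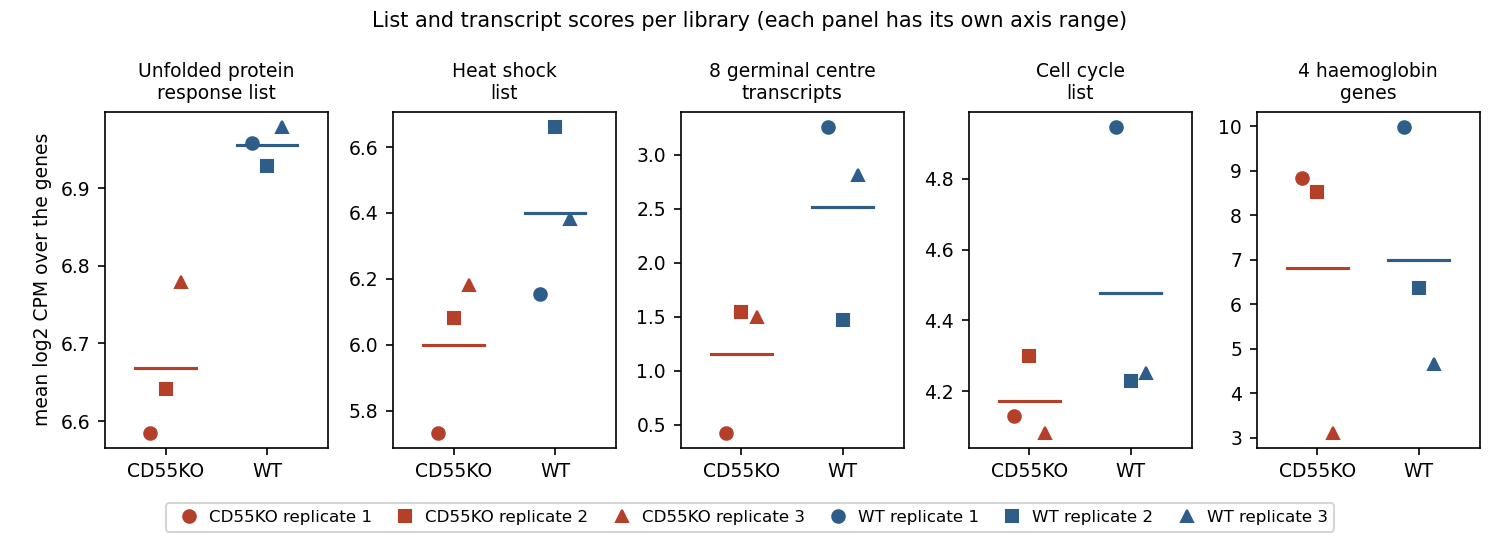
Mean log2 CPM in each CD55KO library (red) and each WT library (blue) over the unfolded protein response list, the heat shock list, 8 germinal centre transcripts, the cell cycle list and 4 haemoglobin genes, with bars at the means of 3 libraries and an axis range of its own in each panel. The genotypes separate in the first panel, and WT replicate 1 stands alone in the cell cycle panel at 4.95.

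Of 12 tested plasma cell and plasmablast markers, 5 had positive and 7 negative log2 fold changes. Xbp1 was the 1 member that fell, and adjusted over the list alone 2 fell, Xbp1 and Prdm1, the latter named after its values were seen. The median was -0.17 (camera adjusted p = 0.042; adjusted p = 0.363 with an estimated correlation). The list was not called without CD55KO replicate 2 (adjusted p = 0.0623), CD55KO replicate 3 (0.180), WT replicate 1 (0.147) or WT replicate 2 (0.0583), nor with the haemoglobin level of each library as a covariate, chosen after seeing the data (0.0862).

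B-1 cell markers formed the 1 called list that was higher in CD55KO, with 9 of 11 positive log2 fold changes and a median of 0.21 (camera adjusted p = 0.0064; adjusted p = 0.305 with an estimated correlation). No member passed over all genes by edgeR or limma-voom, 1 passed by DESeq2, and 4 had an unadjusted p under 0.05, and S100a6 and Cd300lf were the 2 that rose when adjusted over the list alone. S100a6, which encodes a calcium-binding protein, had 10.5 ± 4.0 CPM in CD55KO and 5.57 ± 0.45 CPM in WT (adjusted p over all genes 0.162), and Cd300lf, an inhibitory receptor gene, 50.4 ± 3.99 and 37.4 ± 5.89 CPM (0.138).

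Among 15 tested complement receptors and regulators, Cd55 was the 1 member that passed, over all genes and adjusted over the list alone. The list was lower by camera (median log2 fold change -0.05, adjusted p = 1.4e-08; adjusted p = 0.0964 with an estimated correlation). With Cd55 left out, an alternative chosen after seeing the data, its direction turned and it was not called (adjusted p = 0.936). Cr2, which encodes complement receptor 2 and was named after its values were seen, had 1084 ± 75.6 CPM in CD55KO and 1081 ± 44.5 CPM in WT.

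No shift was called for the genes that mark MZ B cells. Of 20 tested members of the MZ identity list, 11 had positive and 9 negative log2 fold changes, and none passed by edgeR, over all genes or adjusted over the list alone, nor by DESeq2 or limma-voom, while 4 had an unadjusted p under 0.05. The median log2 fold change of 0.0030 and the mean of -0.03 had opposite signs (camera adjusted p = 0.936). Notch2, the receptor that MZ B cells need for their development, had 361 ± 12.3 CPM in CD55KO and 298 ± 25.1 CPM in WT (log2 fold change 0.28 ± 0.09 SE, adjusted p = 0.283). Plxnd1 had 25.0 ± 3.70 and 29.97 ± 0.55 CPM (adjusted p = 0.492).

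Of 18 tested Notch pathway genes none passed over all genes by edgeR, 1 passed by DESeq2 and 3 had an unadjusted p under 0.05. Adjusted over the list alone, 2 rose, Notch2 and Rbpj, the DNA-binding factor of the pathway, which had 34.3 ± 3.03 CPM in CD55KO and 25.4 ± 1.95 CPM in WT (adjusted p over all genes 0.0901). The list was not called (camera adjusted p = 0.142). Of 11 follicular B cell markers none passed over all genes by edgeR and 2 passed by DESeq2. Those that rose when adjusted over the list alone were the transcription factor gene Bach2 (log2 fold change 0.42 ± 0.09 SE, adjusted p over all genes 0.0560) and the IgD gene Ighd (0.37 ± 0.10 SE, 0.187). The follicular list was not called (camera adjusted p = 0.0946), but it was called higher without CD55KO replicate 3 (0.0126) and with the haemoglobin level of each library as a covariate, chosen after seeing the data (0.0386).

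Lists of B cell signalling and activation were not called either. For these lists no member passed over all genes by edgeR, DESeq2 or limma-voom, or adjusted over the list alone. They were 25 BCR signalling components (camera adjusted p = 0.936), 23 genes of Toll-like receptor and BAFF signalling (0.936), 22 NF-kB targets (0.388) and 12 regulatory B cell genes (0.531), with 1, 1, 1 and 2 members at an unadjusted p under 0.05. The same held for 7 transitional and immature B cell markers (0.794, no member at that p) and 11 age-associated and memory B cell markers (0.794, 1 member), whose median of -0.07 and mean of -0.04 were negative while camera placed the list higher. Of 22 immediate early genes none passed over all genes by any of the 3 tools, 4 had an unadjusted p under 0.05 and Fosb rose adjusted over the list alone. That list was not called (0.0946), but it was without CD55KO replicate 3 (0.0051) or WT replicate 2 (0.0366). Of 25 migration and retention receptors Cxcr4 was the 1 member that rose, over all genes and adjusted over the list alone (0.266).

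Among metabolic and survival lists camera called none, while fry called the mTORC1 and amino acid transport list lower (adjusted p = 0.0479). No member passed over all genes by edgeR or limma-voom. Adjusted over the list alone, Pfkl, a phosphofructokinase gene, rose among 20 glycolysis and hypoxia genes (adjusted p over all genes 0.0501), whose median of -0.02 and mean of -0.02 were negative while camera placed the list higher (camera adjusted p = 0.978). Likewise Bach2 rose among 15 FOXO targets (camera adjusted p = 0.149), and Slc1a5, a glutamine transporter gene, fell among 23 mTORC1 and amino acid transport genes (0.149). DESeq2 called 1 member of each of these lists, and 1, 3 and 4 members had an unadjusted p under 0.05. No member passed by any of the 3 tools, or adjusted over the list alone, among 25 nuclear-encoded oxidative phosphorylation genes (0.491), 13 mitochondrially encoded mRNAs (0.0946), 22 cholesterol synthesis genes (0.0524) and 19 apoptosis and p53 target genes (0.491), with 1, 0, 2 and 2 members at an unadjusted p under 0.05. The mitochondrial list was called higher without CD55KO replicate 2 (1.6e-06) or WT replicate 2 (0.0015). The cholesterol list was called lower without CD55KO replicate 1 (0.0261), CD55KO replicate 3 (0.0379) or WT replicate 1 (0.0012), and with library totals as the scaling (0.0448). With the haemoglobin covariate the mitochondrial list was called higher and the cholesterol list lower (0.0386 each).

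Immunoglobulin variable segments took 0.415 ± 0.00092% of the counts in CD55KO and 0.460 ± 0.0098% in WT (SD, n = 3). The libraries did not overlap (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 allow). Of 208 tested segments 36 had an unadjusted p under 0.05 and 1, Ighv1-62-2, fell, from 5.28 ± 1.08 to 1.80 ± 0.69 CPM (log2 fold change -1.54 ± 0.29 SE, adjusted p = 0.022). It was named after its values were seen and was not called by limma-voom, and variable segments can share reads. The number of called segments was 0 without CD55KO replicate 2, CD55KO replicate 3, WT replicate 1 or WT replicate 3, and 2 without WT replicate 2. Of 12 tested genes of the immunoglobulin constant list none passed over all genes by edgeR, 2 passed by DESeq2 and 3 had an unadjusted p under 0.05 (camera adjusted p = 0.531). Adjusted over the list alone, Ighd and Igha rose and Ighg2c fell, from 5.12 ± 3.21 CPM in WT to 1.76 ± 0.077 CPM in CD55KO (adjusted p over all genes 0.340).

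Markers of other cell types were also measured in the sorted cells, and none of their lists was called. The 5 T cell markers (camera adjusted p = 0.127), 10 dendritic cell markers (0.531) and 9 erythrocyte and platelet markers (0.936) held no member that passed by any of the 3 tools or adjusted over the list alone, with 1, 0 and 0 members at an unadjusted p under 0.05. Without WT replicate 1 the erythrocyte and platelet list was called higher (0.0489), the opposite of its direction with all libraries. Of 11 macrophage, monocyte and neutrophil markers none passed over all genes by edgeR and 1 passed by DESeq2. Adjusted over the list alone, 2 rose, Spic, a transcription factor gene of red pulp macrophages (11.8 ± 1.42 CPM in CD55KO and 7.27 ± 1.15 CPM in WT, adjusted p over all genes 0.0901), and the lysosomal gene Cd68 (0.209). The median of that list, -0.0035, and its mean, 0.04, had opposite signs (camera adjusted p = 0.388). With 2 tested members each, the lists of natural killer cell and of stromal and endothelial markers were too small to test, and none of their members passed. Haemoglobin genes took 0.200, 0.155 and 0.00341% of the counts in CD55KO replicates 1 to 3 and 0.439, 0.0358 and 0.01004% in WT replicates 1 to 3.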

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

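Leaving out genes near Cd55, leaving Cd55 out of its list and the haemoglobin covariate were chosen after the results were seen, and the other alternatives were planned. The Cd55 log2 fold change was called under every alternative run for it, from -4.10 without CD55KO replicate 1 to -3.85 without CD55KO replicate 2. Of 13794 tested genes 55 were called (19 higher, 36 lower), against 120 (50 higher, 70 lower) by DESeq2, which called 53 of the 55, 232 (104 higher, 128 lower) with no count filter, which called all 55, and 13 (5 higher, 8 lower) in a test against a fold of 1.5, which asks for a larger change. With the genes near Cd55 left out, 40 genes were called, 11 of them higher, which are the 41 called outside that window except Anxa1 (adjusted p = 0.0644). Leaving out 1 library gave 37 to 53 genes, with 12 to 20 higher and 24 to 35 lower. The other alternatives gave 47 to 70 genes. The cause of the rise with DESeq2 or no filter was not tested.

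The called lists numbered 9, against 0 with an estimated correlation and 2 by fry, the complement list and the mTORC1 list. With an estimated correlation the adjusted p was 0.0964 for complement, 0.305 for B-1 markers, 0.328 for germinal centre markers, 0.363 for plasma cell markers, 0.476 for interferon response, 0.669 for antigen presentation, 0.302 for the unfolded protein response, 0.411 for heat shock and 0.538 for the cell cycle. By fry it was 0.0795 for B-1 markers, 0.169 for germinal centre markers and for heat shock, 0.120 for plasma cell markers, 0.280 for interferon response, 0.370 for antigen presentation, 0.0671 for the unfolded protein response and 0.420 for the cell cycle. Leaving out 1 library gave 8 to 11 lists, and 6 of the 9 were called each time. The exceptions were plasma cell markers (0.0134 without WT replicate 3 to 0.180 without CD55KO replicate 3, and 0.0862 with the haemoglobin covariate), antigen presentation (0.000192 without WT replicate 1 to 0.414 without WT replicate 3) and the cell cycle (1.6e-11 without WT replicate 2 to 0.147 without WT replicate 1). The complement list reversed, at an adjusted p of 0.936, both with Cd55 left out and with the genes near Cd55 left out, which shows that its call rests on Cd55. Called genes near Cd55 numbered 13, and 8 to 12 without 1 library. Called variable segments numbered 1, and 0 to 2 without 1 library. Apart from the complement list, the cause of these differences was not tested.

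Whether the replicate numbers pair the libraries stays open, since the labels do not say so. Deviations of libraries with the same number correlated across genes at 0.07, -0.12 and 0.17. CD55KO replicates 1 and 3 and WT replicate 3 correlated best with their own number, and the other libraries did not. So few correlations cannot exclude pairing. With the number as a replicate block 64 genes were called, 51 of them among the 55, with 2 variable segments. H2bc4, Zc3h11a and Gcsam were not called, at adjusted p of 0.0779, 0.108 and 0.0978, nor was the predicted gene Gm29253 (0.0630), named after its values were seen. Hsph1 and Hspa8, not among the 55, were called, at 0.000711 and 0.0126. The plasma cell list was not called with the block (adjusted p = 0.0820) while the follicular list was (0.0490). For the 79 single-gene results followed, 707 comparisons kept direction and side of the threshold, 61 became weaker and 19 stronger. At the depth of these libraries a count of 0 allows up to 0.0958 to 0.146 CPM, and no alternative varied the depth.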

Other observations

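Of the tests described here, those of cell handling and of immediate neighbours were chosen after the result was seen. So were the second test of germinal centre transcripts and the tests of each list without 1 library. The window test was planned because a targeted allele can carry flanking DNA. What flanking DNA predicts for that test was written down only after the result was seen. The genes of the next paragraph were also chosen after their values were seen.

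Stip1, Ahsa1 and Fkbp4, which encode proteins that bind HSP90, were among the genes that fell. Stip1 fell from 170 ± 7.76 to 120 ± 11.2 CPM (SD, n = 3; log2 fold change -0.50 ± 0.08 SE, edgeR adjusted p = 0.0064), Ahsa1 from 217 ± 7.45 to 160 ± 11.0 CPM (adjusted p = 0.014) and Fkbp4 from 194 ± 17.5 to 129 ± 18.4 CPM (adjusted p = 0.015). Rpn1, a subunit of the oligosaccharyltransferase of the ER, fell from 153 ± 4.77 to 113 ± 7.44 CPM (adjusted p = 0.010). Stip1 passed in all 6 fits without 1 library and the others in 4 of 6, with adjusted p up to 0.0884 for Ahsa1 (not called without CD55KO replicate 3 or WT replicate 2), 0.0884 for Fkbp4 (without WT replicate 1 or 2) and 0.121 for Rpn1 (without CD55KO replicate 2 or WT replicate 1). Away from chromosome 1, called genes also lay side by side. On chromosome 11, Tgtp1, an interferon-inducible GTPase gene next to 9930111J21Rik2, fell from 7.78 ± 1.67 to 1.89 ± 0.30 CPM (adjusted p = 0.00011), and on chromosome 12, Srp54a fell from 73.4 ± 2.96 to 50.2 ± 2.06 CPM (adjusted p = 0.0015) beside Fam177a and Srp54b. Members of these families resemble each other, so their values are uncertain. Of the 41 called genes outside the 10 Mb around Cd55, 5 lay within 1 Mb of another, against a mean of 2.79 in 10000 random draws (permutation p = 0.17).

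In the ER list 9 of 22 members fell (list adjusted p = 0.302 with an estimated correlation, 0.0671 by fry), and fewer plasma cells or a difference in cell handling are candidate explanations. The planned test, the mean log2 difference of plasma cell transcripts less that of the ER list, came to -0.386 ± 0.247 (SE), in the direction that fewer plasma cells predict but within 2 SE, and moved to -0.20 ± 0.271 without WT replicate 1 and to -0.61 ± 0.156, beyond 2 SE, without WT replicate 3. Fewer plasma cells therefore stay open. The 8 tested transcripts differed by -0.672 ± 0.234 (SE) in mean log2 CPM, CD55KO minus WT. They summed to 77.8 ± 3.92 CPM in CD55KO and 102 ± 30.2 CPM in WT (SD, n = 3), a difference of -24.0 ± 17.6 CPM (SE). The ER list summed to 5039 ± 382 and 6275 ± 259 CPM. Its difference of -1236 ± 267 CPM (SE) was larger than all that the 8 transcripts held in WT. Plasma cells could account for that loss only if they held far more RNA of the ER list than of these 8 genes, which was not tested. A sort for MZ cells is meant to remove plasma cells, and Igha, 1 of the 8, had 9.90 ± 0.40 and 7.40 ± 0.43 CPM and rose when adjusted over its list alone. Handling, and as untested an effect of the missing CD55, stay open too. Heat shock and ER scores correlated within genotypes at r = 0.447, between the bounds set for and against handling (6 libraries, exact permutation p = 0.556, Spearman's rho 0.371, p = 0.611, r = -0.63 without the 2 farthest libraries). Of the cold-inducible genes Rbm3 rose. Cirbp was also higher, with 143 ± 37.6 CPM in CD55KO and 74.4 ± 7.60 CPM in WT (log2 fold change 0.94 ± 0.20 SE). Its libraries did not overlap, but it did not pass (adjusted p = 0.247).

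Called genes clustered around Cd55, where DNA of another strain carried along with the targeted allele, or an effect of the allele on its neighbours, may be the reason. An effect on immediate neighbours would place the genes close by, and 7 of the 13 lay within 1 Mb. Between 1 and 10 Mb, however, genes were still called more often than elsewhere (6 of 94, odds ratio 22.65, 95% interval 7.66 to 55.59), which argues against that explanation for the more distant genes. Flanking DNA predicts calls in both directions over the region, as found (odds ratio 42.3, 95% interval 20.2 to 83.6, which overlapping genes next to Cd55 may raise). It remains a hypothesis, since the strain history of the allele is not given in the sources used here. No other of the 10 splits of the libraries called a gene in the window, against 13, but 10 splits cannot give a share under 0.05 (1 split was as large, the real one).

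By camera with the preset correlation the germinal centre and cell cycle lists were lower in CD55KO, with 1 of 13 and 0 of 29 members past the threshold and adjusted p of 0.328 and 0.538 with an estimated correlation, for which fewer germinal centre B cells in the sorted CD55KO cells, or 1 library, may account. If GC cells were fewer, their transcripts would fall by 1 factor. The planned test on 8 transcripts went against that (Cochran's Q, chi-square p = 0.000412), but its bound was wrong for Neil1, which had 17.3 to 20.8 CPM in every CD55KO library, above the other 7, a level that would hide a small share of GC cells. Without Neil1 the 7 others gave a chi-square p of 0.675 (Cochran's Q) around a common log2 fold change of -1.67. That second test cannot decide, since the SEs of the 7 were wide, from 0.36 to 0.90, against 0.17 for Neil1. Cochran's Q also takes their errors as independent, although all 7 were measured in the same libraries. Fewer GC cells stay open, although a sort for MZ cells is meant to remove them. The planned test of 1 library took both lists together and was met through the cell cycle list, whose highest adjusted p was 0.147, without WT replicate 1. The GC list was called in all 6 fits (highest 0.000139). Camera with the preset correlation also calls lists in groupings that mix the genotypes, so these calls cannot exclude 1 library. The difference in mean log2 CPM of the GC list, CD55KO minus WT, was -0.94 with all libraries. It stayed negative in all 6 fits, from -1.27 without WT replicate 2 to -0.70 without WT replicate 1. The genotypes nevertheless overlapped in that mean, with 2.72 in WT replicate 2 and 2.73 in CD55KO replicate 2.

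The real grouping gave 55 called genes and the highest of the other 9 splits of the 6 libraries gave 3. For called lists the real value was 9 and the highest other 11, and 2 of the 10 splits, the real one included, gave at least 9. With 10 splits no share under 0.05 can be reached. The other splits gave 4 to 11 lists, so list calls with the preset correlation also appear in groupings that mix the genotypes.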
